A study of Monascus purpureus with 9 samples.

How the data were processed

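The series holds 9 RNA-seq libraries of mycelium of Monascus purpureus, a filamentous fungus grown for its azaphilone pigments. Per the labels, 3 libraries came from the wild type (WT), 3 from a Set1 knockout and 3 from a Swd3 knockout, all from total RNA of mycelium cultured for 2 days in PDB medium. Per the labels' protocols, libraries were made from total RNA with a SMARTER mRNA-seq kit. Groups and replicate numbers were taken from the sample titles, and each column of the table carries the name of one title. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

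The authors deposited one table of FPKM values (fragments scaled by transcript length and by the library's mapped fragments) with a row per gene identifier and a column per library. Per the submitters' processing notes, FastQC, HISAT2 and StringTie were used. Their versions and settings, the genome build, the annotation and the use of strand are not given in the sources used here. The deposited FPKM values reach down to 1e-06 and showed no steps of whole reads (among 70 genes under 0.15 FPKM in WT libraries 1 and 2, the ratios of both values spread over 31 bins of 0.1 log2 units, and the fullest held 8.57%), so read counts and sequencing depth are unknown, and no count-based test, counting interval or detection floor was computed. An exact 0 in such a table can be a failed estimate, so it is described below as listed at 0.

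The table has 9869 rows, 8918 named gene_ with a number and 951 named NewGene_ with a number. It pairs no row with a gene name, a coordinate or a length. Of these rows, 0 matched the locus tags, symbols or accessions of the reference gene list of assembly ASM2599979v1, which has 9270 entries. The 33 gene lists fixed before the data were examined (among them COMPASS subunits, the pigment, citrinin and monacolin clusters, secondary metabolite enzymes, conidiation, ribosome and energy metabolism) therefore had 0 members, no list was tested, and the transcripts of Set1, Swd3 and the pigment genes were not analysed here. Checks of gene length and GC content were void for the same reason. A row is called a gene below, without a claim about what it encodes.

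Genes entered the tests with an FPKM of at least 1 in at least 3 of the 9 libraries, which kept 9153 genes (8580 gene_ and 573 NewGene_) and left out 716. Values were taken as log2(FPKM + 1), with no further scaling between libraries. One linear model with a mean per group was fitted to all 9 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with an intensity trend), and the 3 comparisons were the Set1 knockout with WT, the Swd3 knockout with WT and the Swd3 with the Set1 knockout. P-values are two-sided and were adjusted by Benjamini-Hochberg over the genes tested in each comparison, with a threshold of 0.05. Fold changes and standard errors (SE) are on the log2(FPKM + 1) scale, which understates changes of low genes. In simulated data for the Set1 comparison, built on the 9153 tested genes with 200 changed, the fit called 64.2% of the 1.5-fold, 91.0% of the 2-fold and 95.5% of the 4-fold changes, and 9 of the 8953 unchanged genes. The data had 7422 changed genes in this comparison. The adjusted threshold is stricter when few genes change, so these rates do not carry over to the data.

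The rule for naming genes, set before the data were examined, took at most 2 genes up and 2 down per comparison because the table has no descriptions. They are the largest log2 fold changes among genes with an adjusted p under 0.05, a mean FPKM of at least 5 in the higher group and no overlap between the values of both groups. Classes by mean FPKM over the 9 libraries, the NewGene_ class, the counts of genes at 0 and the order of gene numbers were chosen after seeing the data. The NewGene_ class was tested with camera at a preset correlation of 0.01 and set beside 10000 random lists of gene_ rows matched on mean FPKM in 50 bins. Library-level measures were compared by exact permutation tests, which cannot give a p below 0.1 with 3 libraries against 3.

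The similarity of both knockouts was set beside 100 simulations of unchanged groups measured against shared WT libraries. Alternatives covered the pseudocount (0.1 and 0.5), the filter, 3 scalings (a common total, median of ratios, quantile normalization), a fit of the compared groups alone, the replicate number as a block, robust variance moderation and each library of the compared groups left out in turn. The replicate numbers were not taken as a pairing in the main fit, because the labels name no shared batch. Of the 9 same-number pairs of libraries, 4 had correlated deviations above 0.1. No batch or date is given in the labels.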

Results

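RNA-seq profiles of Monascus purpureus mycelium were compared between the wild type and strains lacking Set1 or Swd3. Both proteins are core subunits of COMPASS, the complex that methylates histone H3 at promoters of transcribed genes, with Set1 as its catalytic subunit and Swd3 as a structural one. The design asked how the loss of each subunit alters gene expression in a fungus studied for its pigments. Each group had 3 libraries. The summed FPKM per library ranged from 705678 to 729434, with the Set1 knockout libraries above all others, and the 10 most abundant genes took 17.7% to 19.3% of it. Sequencing depth is unknown because the table holds FPKM only.

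The libraries fell by genotype. On the log2(FPKM + 1) scale, Pearson correlations across genes were 0.9933 to 0.9966 between WT libraries, 0.9941 to 0.9959 between Set1 knockout libraries and 0.9923 to 0.9949 between Swd3 knockout libraries. A knockout library and a WT library correlated at 0.8858 to 0.8955, whereas libraries of the 2 different knockouts correlated at 0.9886 to 0.9916. The first principal component held 89.9% of the variance and separated WT from both knockouts, and the second held 3.24% and separated Set1 from Swd3 knockouts. The median SD between replicates was 0.09 in WT, 0.09 in Set1 knockouts and 0.11 in Swd3 knockouts (log2 units, n = 3 each).

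Neither deletion target could be located by name, so the labels were looked at through genes missing from one knockout only, a criterion chosen after the values were seen. Among 6292 genes with at least 5 FPKM in every WT and Swd3 knockout library, 1 gene fell in the Set1 knockout under 5% of the lower of its means in the other groups. This was gene_8282, at 17.7 ± 2.32 FPKM in WT, 7.96 ± 1.73 in the Swd3 knockout and listed at 0 in all 3 Set1 knockout libraries (SD, n = 3). In the Swd3 knockout, 0 of 6305 genes met the same criterion, and the lowest, gene_8239, kept 24.3% of its WT mean, the lower of its means in the other groups. The table does not say what either gene encodes. A deletion target under 5 FPKM in any library of the other groups could not be found this way, so the search settles neither label.

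Fewer genes were listed at 0 in the knockouts than in the wild type, although an exact 0 in this table can be a failed estimate. WT libraries listed 431 ± 8.72 genes at 0, against 161 ± 10.1 in Set1 knockouts and 159 ± 3.0 in Swd3 knockouts (SD, n = 3). Genes at 1 FPKM or more numbered 8362 ± 32.1 in WT, 9076 ± 17.1 in Set1 knockouts and 9078 ± 15.9 in Swd3 knockouts. At the other end, genes at 100 FPKM or more numbered 1121 ± 17.1 in WT and fewer in the knockouts, with 1016 ± 15.6 and 1008 ± 32.7 in the same order. The median gene stood at 14.6 ± 0.463 FPKM in WT, 12.8 ± 0.374 in Set1 knockouts and 13.2 ± 0.668 in Swd3 knockouts, and the 100 most abundant genes took 39.2 ± 0.861%, 41.9 ± 0.671% and 42.5 ± 0.984% of the summed FPKM. In each of these comparisons with WT the groups did not overlap, and the exact two-sided permutation p was 0.1, the smallest that 3 libraries against 3 allow.

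A set of genes was listed at 0 in all WT libraries and above 0 in at least 1 library of each knockout. It held 160 genes, 86 named gene_ and 74 named NewGene_, with a median of 0.427 FPKM in the Set1 and 0.460 FPKM in the Swd3 knockout. Only 6 genes were listed at 0 in all 6 knockout libraries and above 0 in WT. Asking for 0 in 6 libraries is stricter than asking for it in the 3 WT libraries, here and in the reverse pattern below. Genes listed at 0 in all libraries of a single knockout and of no other group numbered 12 for Set1 and 10 for Swd3. Within the 160, 35 genes had at least 1 FPKM in all 6 knockout libraries, with medians of 3.03 FPKM in the Set1 knockout (range 1.28 to 14.2) and 3.07 FPKM in the Swd3 knockout (range 1.36 to 16.9). The reverse pattern, at least 1 FPKM in all WT libraries and 0 in all knockout libraries, was found for 0 genes. With a limit of under 0.1 FPKM in place of 0, the 2 numbers were 63 and 0.

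**Figure D1:**
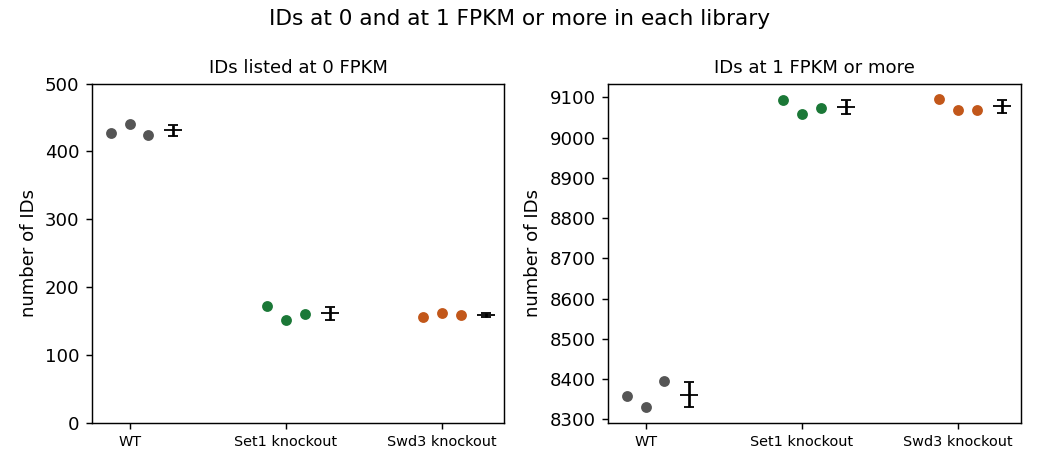
Number of genes listed at 0 FPKM (left) and at 1 FPKM or more (right, axis not starting at 0) in each of the 9 libraries, with points for libraries and black marks for the mean ± SD of each group. WT libraries list 425 to 441 genes at 0, and the knockout libraries 152 to 172.

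Most genes tested changed in the Set1 knockout. Relative to WT, 3456 genes rose and 3966 fell in the Set1 knockout, together 81.1% of the 9153 tested (limma, adjusted p under 0.05). Many changes were small, with a median absolute log2 change of 0.72 among the changed genes, and 1731 genes did not pass. Over all genes tested, large changes were more often gains, since 1423 genes rose and 901 fell at least 2-fold, 367 rose and 83 fell at least 4-fold, and 86 rose and 19 fell at least 8-fold. Among genes with a mean of at least 5 FPKM the 2-fold changes were near even, with 876 rises and 840 falls. The median log2 fold change of all genes was -0.06, and scaling by the median of ratios moved it by 0.08, so the balance of all rises and falls follows the scaling, with 3769 rises and 3686 falls after that one.

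By the naming rule and on the log2(FPKM + 1) scale, the largest gains in the Set1 knockout were those of gene_1082 and gene_404. Gene_1082 went from 2.40 ± 0.176 FPKM in WT to 406 ± 13.4 FPKM (SD, n = 3), a log2 fold change of 6.91 (SE 0.05, limma adjusted p = 6.93e-18). Gene_404 went from 9.85 ± 0.409 to 932 ± 4.71 FPKM, a 94.5-fold ratio of means (limma adjusted p = 7.44e-18). The largest falls were those of gene_8145, from 127 ± 8.03 to 3.39 ± 0.283 FPKM, and gene_1122, from 193 ± 13.8 to 7.82 ± 0.382 FPKM. Their log2 fold changes were -4.87 (SE 0.09) and -4.46 (SE 0.07), with limma adjusted p of 5.42e-14 and 2.53e-14.

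Genes of low abundance rose and genes of middle abundance more often fell in the Set1 knockout. Of 154 tested genes with a mean under 1 FPKM over the 9 libraries, 123 rose and 7 fell. A gene of this class was tested only if it reached 1 FPKM in at least 3 libraries, and without that filter 324 of 817 rose and 23 fell. Of 1677 genes at 1 to 5 FPKM, 997 rose and 256 fell. Among genes at 5 to 20 FPKM 1070 rose and 1604 fell, and among those at 20 to 100 FPKM 823 rose and 1624 fell. Many of these falls were small. At least 2-fold, 503 rose and 428 fell at 5 to 20 FPKM, and 263 rose and 330 fell at 20 to 100 FPKM. Genes at 100 FPKM and over were near even, with 443 up and 475 down. The rise of the genes under 5 FPKM depended on how the libraries were made comparable. It held with either scaling by one factor per library, but under quantile normalization, which gives every library the same distribution of values, 441 of these genes rose and 690 fell, against 1120 and 263 here.

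Rows named NewGene_, whose origin the table does not explain, rose more often than they fell. In the Set1 knockout 340 of 573 rose and 78 fell, with a median log2 fold change of 0.53 against -0.10 for gene_ rows (camera, adjusted p = 2.34e-07, and adjusted p = 0.0074 with an estimated correlation). Without the filter 451 rose and 85 fell, among at most 951 such rows (475 and 79 in the Swd3 knockout). Under quantile normalization the balance turned, with 147 rises and 203 falls in the Set1 knockout. These rows were of low abundance, at a median of 2.61 FPKM against 17.8 FPKM. Their median change in the Set1 knockout lay at percentile 76.7 of 10000 lists of gene_ rows matched on mean FPKM. In that knockout the rise was not set apart from that of other genes of the same level. Among those with a mean of at least 5 FPKM, 83 rose and 44 fell.

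**Figure D2:**
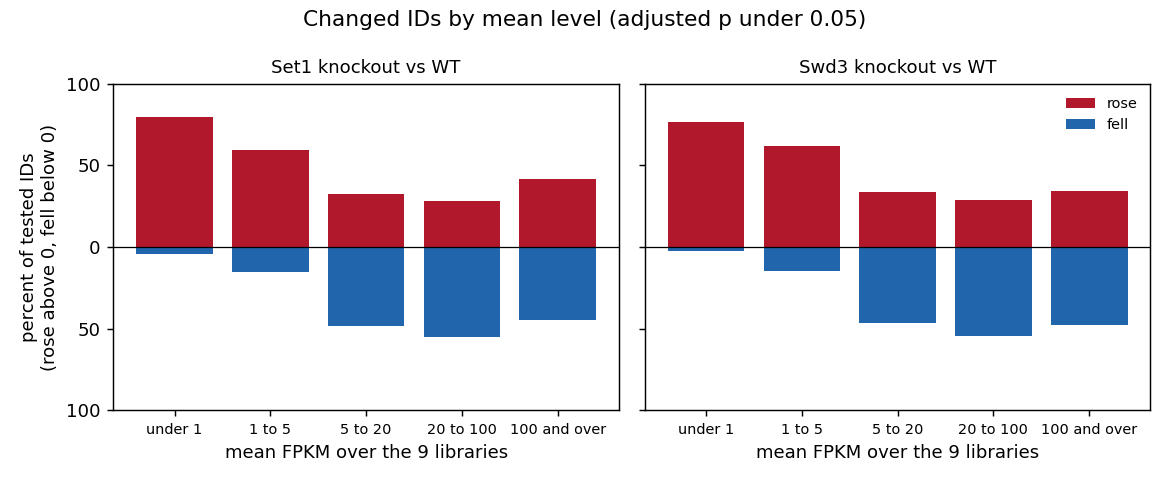
Percent of tested genes that rose (red, upward) or fell (blue, downward) against WT at an adjusted p under 0.05, by mean FPKM over the 9 libraries, in the Set1 knockout (left) and the Swd3 knockout (right). Rises prevail under 5 FPKM and falls between 5 and 100 FPKM. Under quantile normalization, falls outnumbered rises among the genes called under 5 FPKM.

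The Swd3 knockout had a similar number of changed genes. Relative to WT, 3499 genes rose and 3889 fell in the Swd3 knockout, 80.7% of those tested (limma, adjusted p under 0.05), and 1765 did not pass. At least 2-fold changes comprised 1489 rises and 847 falls (906 and 783 among genes with a mean of at least 5 FPKM), and at least 8-fold changes 106 rises and 20 falls. Among genes under 1 FPKM 118 of 154 rose and 4 fell (323 and 24 of 817 without the filter), and among those at 1 to 5 FPKM 1042 rose and 242 fell. Genes at 20 to 100 FPKM went the other way, with 848 up and 1602 down, as did genes at 100 FPKM and over, with 368 up and 511 down. Of the NewGene_ rows 358 rose and 75 fell, and 86 and 42 with a mean of at least 5 FPKM. Camera over all of them gave an adjusted p of 8.67e-08, and of 0.0074 with an estimated correlation. Their median log2 fold change of 0.59 lay at percentile 98.5 of the matched lists, whose median was 0.53. Unlike in the Set1 knockout, the rise was thus larger than in most matched lists, by a small amount. Under quantile normalization the balance again turned, with 462 rises and 664 falls under 5 FPKM. The NewGene_ rows then had 154 rises and 189 falls.

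By the same rule and scale, the largest gains in the Swd3 knockout were those of gene_1082, at 526 ± 5.85 FPKM, and gene_7122. Gene_7122 went from 29.7 ± 1.07 FPKM in WT to 4047 ± 99.5 FPKM (SD, n = 3), a log2 fold change of 7.04 (SE 0.04, limma adjusted p = 1.44e-18). The largest falls were those of gene_8145, to 5.07 ± 0.504 FPKM, and gene_4620, from 130 ± 1.98 to 6.29 ± 0.680 FPKM. Their log2 fold changes were -4.41 (SE 0.09) and -4.17 (SE 0.07), with limma adjusted p of 1.13e-13 and 5.59e-14.

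Both knockouts changed largely the same genes in the same direction. In total 3190 genes rose in both and 3637 fell in both, while 32 genes were called in opposite directions. Independent lists of these sizes would share 1321 rises and 1685 falls. At least 2-fold, 1308 genes rose and 736 fell in both. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.977 and Spearman's rho = 0.974, and 94.0% had the same sign. Both comparisons used the same WT libraries, and simulated unchanged groups gave a mean r of 0.497 and a same-sign share of 66.8%. The 3 WT libraries could not be split into parts of at least 2 libraries each, so part of the excess of shared calls over independent lists may come from the shared controls. Independent scatter of the shared controls adds the same amount to the covariance of the fold changes with or without effects. That covariance was 0.958 against a simulated mean of 0.00837, which leaves 0.950. A deviation common to all 3 WT libraries was not simulated. The slope of the Swd3 on the Set1 response was 0.99.

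**Figure D3:**
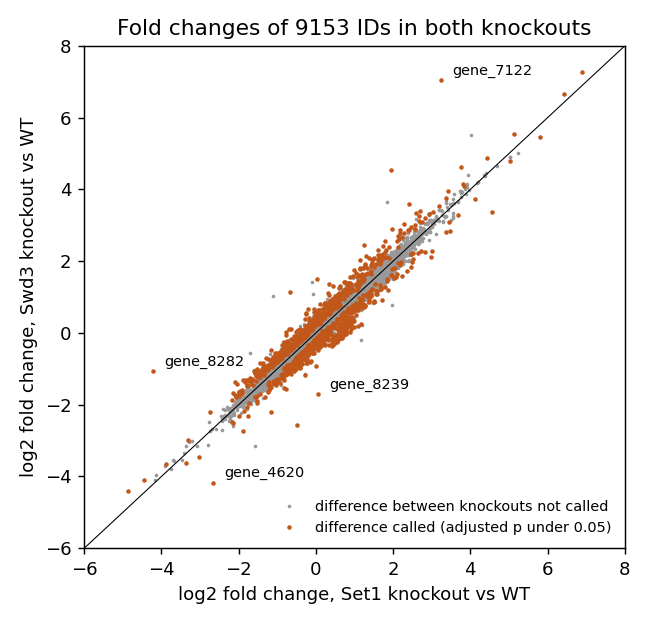
Log2 fold change against WT of each of the 9153 tested genes in the Set1 knockout (x axis) and the Swd3 knockout (y axis), on the log2(FPKM + 1) scale, with genes called different between the knockouts in orange and the line of equal change in black. Most genes lie along the line, and gene_7122, gene_8282, gene_8239 and gene_4620 lie apart from it.

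The direct comparison of the knockouts asked where the knockout strains differ. The labels name no separate cultures or independent strains of a knockout. The subunit lost and each strain's own history or culture therefore cannot be told apart here. Between them, 1173 genes differed (limma, adjusted p under 0.05), 610 higher and 563 lower in the Swd3 knockout, and 7980 did not pass. The differences were small, with a median absolute log2 value of 0.33, and 13 genes differed at least 2-fold (8 higher, 5 lower in Swd3). Of the 1173 genes, 806 had changed in the same direction in both knockouts, with the larger change in the Swd3 knockout for 434 of them. The 32 genes called in opposite directions against WT all passed in the direct comparison. This is no separate evidence, because in the shared fit their direct difference is the size of both changes added together. Leaving out Swd3 replicate 2 lowered the 1173 to 733, and leaving out Set1 replicate 3 lowered it to 758. The split followed the scaling, with 772 higher and 430 lower when every library was set to a common total.

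On the log2(FPKM + 1) scale the largest difference was that of gene_7122, which stood at 4047 ± 99.5 FPKM in the Swd3 and 291 ± 10.2 FPKM in the Set1 knockout (SD, n = 3), a 13.9-fold ratio (limma adjusted p = 3.83e-15). Gene_8282 was listed at 0 in all Set1 knockout libraries and at 7.96 ± 1.73 FPKM in the Swd3 knockout (limma adjusted p = 2e-08). Its log2 difference has no upper bound, and it came second to gene_7122 here (3.15 against 3.80) but first with a pseudocount of 0.5 (4.06 against 3.80) or 0.1 (6.31 against 3.80). Gene_8239 was lower in the Swd3 knockout, at 2.66 ± 0.319 against 11.5 ± 1.02 FPKM (limma adjusted p = 1.24e-07). Its WT level was 11.0 ± 0.815 FPKM, and its log2 change in the Set1 knockout was 0.06 (SE 0.10), which did not pass. Gene_4620 was lower in both knockouts than in WT and stood at 19.6 ± 1.11 FPKM in the Set1 and 6.29 ± 0.680 FPKM in the Swd3 knockout (limma adjusted p = 7.16e-08).

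**Figure D4:**
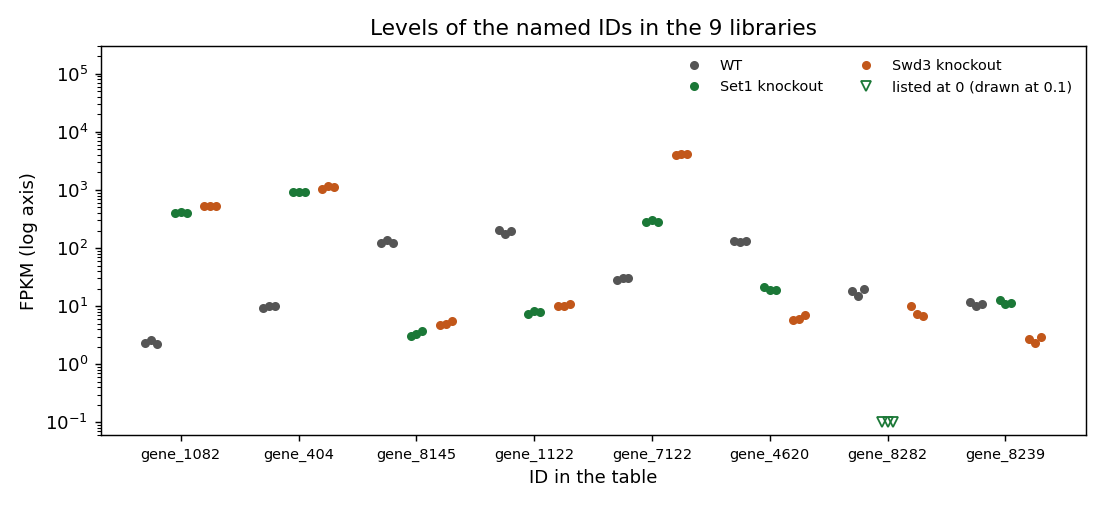
FPKM of the 8 named genes in each of the 9 libraries on a log axis, with points for libraries coloured by genotype and open triangles at 0.1 for values listed at 0. Gene_1082 and gene_404 are high in both knockouts, and gene_7122 is highest in the Swd3 knockout at 4047 ± 99.5 FPKM.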

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

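The tests of background, scaling, depth, shared WT libraries, strain history and other splits were chosen after the results were seen.

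The 4 genes named for the direct comparison of the knockouts were chosen for a large difference and a small adjusted p, so these values restate the choice and are no separate evidence. The Swd3 minus Set1 difference on the log2(FPKM + 1) scale was 3.80 for gene_7122, 3.15 for gene_8282, -1.77 for gene_8239 and -1.50 for gene_4620, with limma adjusted p of 3.83e-15, 2e-08, 1.24e-07 and 7.16e-08. The value for gene_8282 rests on a group listed at 0 and depends on the pseudocount, being 6.31 with a pseudocount of 0.1. Over the 1173 genes that differed, the average response explained 1.29% of the variance of the difference.

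Genes at low mean levels mostly rose in both knockouts. The 2 one-factor scalings tried do not account for it, because at least 80.1% of the changed genes under 5 FPKM still rose under both. They moved the median log2 fold change of all genes against WT by only -0.034 to 0.080. The median change at 1 to 5 FPKM was 0.55 in the Set1 and 0.59 in the Swd3 knockout. A larger single factor was therefore not tested. It would move genes of all levels the same way, but the medians at 20 to 100 FPKM were -0.26 in Set1 and -0.24 in Swd3. These values argue against a single factor as the source of the opposite medians at 1 to 5 and 20 to 100 FPKM. The one-factor test is narrower than the first one written. That first test asked for the direction of the lowest and the most abundant genes to hold under every scaling tried. It counted at least 2-fold changes and asked for mostly falls at the most abundant genes, but 57.3% of those at 100 FPKM and over were gains in the Set1 knockout without any added scaling. The first test could therefore not have excluded scaling, and after results were seen the test was limited to one-factor scalings and the abundant genes were left out of the pattern. A lower depth of the WT libraries would lower no expected FPKM except by loss to 0, yet among the 1652 genes under 5 FPKM that were above 0 in all WT libraries at least 78.3% of the changed genes rose. For the 179 tested genes under 5 FPKM at 0 in a WT library, depth and low expression in WT cannot be told apart, because choosing genes at 0 in WT fixes their direction and no read counts are given. A first test of depth, written before its result, was dropped because it chose genes by their WT level and so left out those that depth would set to 0. Uniform background reads in the knockout libraries stay open. They would lift every gene near 0. Of 435 genes under 0.1 FPKM in WT and above 0 in at least 1 of the 9 libraries, 68 (15.6%) stayed under 0.1 FPKM in both knockouts. That share lies between the bounds set for and against such reads. It leaves out 51 genes listed at 0 in all 9 libraries. Counting them as not lifted would add 51 to both the 68 and the 435. The share would then rise toward or past the bound set against such reads. Its place between the bounds may therefore depend on leaving these 51 genes out. An exact 0 can be a failed estimate, so the test cannot decide. A further test of background, made after the share of 15.6% was seen, was dropped because it selected genes by the gain it measured. Also open are a difference in the whole distribution of values, technical or biological, which quantile normalization would remove (441 rises and 690 falls in the Set1 knockout), and a biological effect of losing COMPASS, which remains a hypothesis.

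The Set1 and Swd3 responses were nearly the same. Independent scatter of the shared WT libraries does not account for it as the only source. The covariance of the fold changes was 75.8 times the highest of 100 simulations without effects. Those simulations drew the deviation of each library independently, so a deviation common to all 3 WT libraries stays open. The loss of one shared complex and a strain history or handling common to both knockouts and not to WT cannot be told apart, because both predict the 99.5% of genes called in both knockouts that moved the same way, and no transformed control strain is among the 9 libraries.

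With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each of the 3 comparisons 1 split, the real one, gave as many changed genes. The real values were 7422 for Set1 with WT, 7388 for Swd3 with WT and 1173 for Swd3 with Set1, and the highest of the other splits gave 1 in each. Every other split mixes libraries of both groups, so the group difference enters its spread. Few calls there were fixed in advance, and the contrast is no separate evidence.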

How the results depend on the processing

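The alternatives for the changed genes were set before the data were examined, and those for genes at 0 in WT, NewGene_ rows and neighbouring numbers were added after. No named gene changed direction or lost its call in the comparison it was named for. A mean FPKM of at least 5, which tests fewer low genes, lowered the at least 2-fold rises from 1423 to 876 (Set1, beside 840 falls) and from 1489 to 906 (Swd3, beside 783 falls), and the rises in both knockouts from 3190 to 2117. It left 83 rises and 44 falls of NewGene_ rows in Set1 (340 and 78 before) and 86 and 42 in Swd3 (358 and 75 before). With a pseudocount of 0.1, 9 rather than 5 genes were at least 2-fold lower in Swd3 than in Set1. The 35 genes at 0 in WT became 63 with a limit of under 0.1 FPKM, and 9 with at least 5 FPKM in the knockouts. Leaving out in turn each of the 6 libraries of the compared groups gave 733 to 1179 genes that differed between the knockouts, 362 to 659 higher and 371 to 678 lower in Swd3 (without Set1 replicate 2, 406 higher). It gave 7101 to 7333 changed genes for Set1 and 7080 to 7362 for Swd3 against WT. Without the filter, 324 of 817 genes under 1 FPKM rose and 23 fell in the Set1 knockout, against 123 and 7 of 154 with it. Quantile normalization kept 6134 of the 7422 Set1 calls, 60 of them with the other sign. It turned the balance of rises and falls among the low genes, mostly by changing which genes were called. The cause was not tested. With the replicate number as a block, the counts were 7521, 7518 and 1369 for Set1 with WT, Swd3 with WT and Swd3 with Set1. The labels name no pairing by number. The best match in another group had the library's own number in 9 of 18 cases, and in both other groups for 1 of 9 libraries. A weak structure shared by number stays open. Alternatives for the gene lists and for the Set1 and Swd3 transcripts were not run, as no row could be matched to them. Unknown depth limits statements on genes near 0.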

Other observations

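The tests in this part were chosen after the result was seen, except the removal of the trend on expression level.

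Genes with neighbouring numbers in the table changed together. For gene_ rows whose numbers differ by 1, the log2 fold changes of 7454 pairs correlated at 0.387 in the Set1 knockout and 0.406 in the Swd3 knockout, above the highest of 1000 shuffled orders (0.0361 and 0.0478, permutation p = 0.001 each, the smallest they can give). The correlation was 0.102 and 0.103 at a distance of 10 numbers and 0.0038 and 0.0085 at a distance of 20. In the Set1 knockout, genes that rose at least 2-fold formed 100 runs of at least 3 consecutive numbers, against a mean of 18.8 and a highest value of 33 in shuffled orders, and these runs held 31.6% of such genes. Falls of that size formed 33 runs against a highest of 15, holding 12.5% of the genes, but only 2 runs of at least 5 numbers against a highest of 2, and their longest run of 5 was shorter than the longest of 7 in shuffled orders. In the Swd3 knockout falls formed 30 runs of at least 3 numbers against a highest of 14, and 3 runs of at least 5 numbers against a highest of 1, with a longest of 5 against 6. Of 406 genes in rising runs of the Set1 knockout and 448 of the Swd3 knockout, 376 were shared. The longest run, singled out after its values were seen, went from gene_9451 to gene_9464 in both knockouts, 14 genes with WT means of 0 to 8.0 FPKM and Set1 knockout means of 1.72 to 76.1 FPKM. Of the 34 gene_ rows at 0 in WT and at least 1 FPKM in all knockout libraries, 22 lay in rising runs of the Set1 knockout.

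A hypothesis is that the numbers follow the order along the genome and that blocks of neighbouring genes respond together, as secondary metabolite clusters or silent regions might. The table gives no coordinates, so the order itself is an assumption. Reads shared between adjacent gene models would act over a distance of 1. The correlation at a distance of 3 was 0.207 against a shuffled maximum of 0.0441 in the Set1 knockout, so they are not the only source. They may still add to the correlation at a distance of 1 and to the runs. Neighbours of similar abundance do not carry most of the correlation, as 88.7% of it was left at a distance of 1 in the Set1 knockout after the trend on mean expression was removed. Shared regulation, chromatin state and gene families in tandem remain open, and none of them was tested.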
